A study of Caenorhabditis elegans with 4 samples.

How the data were processed

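ChIP-seq with an antibody against ZIM-3 was carried out on C. elegans adults of the strain fem-2(b245), labelled as young adults. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 minutes and sonicated, and libraries of ChIP and input DNA were made with Illumina adapters and PCR. Of the 4 samples, the 2 ChIP samples each have 1 peak list and there is 1 list for the whole series; the 2 input samples have no list here and entered no comparison. The labels do not say whether the replicates came from separate cultures.

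The authors deposited each peak with a position and a score. Per the file headers, coordinates are on WormBase WS220. The lists name MACS as the caller of the peaks of each replicate and MACS v2 as the caller of the series-wide peaks, with no parameters. The submitters' processing notes name the aligner BWA and the build ce10, without versions. How the series-wide list combined the replicates, which control was used and which filters were applied is not given in the sources used here. The scale of the deposited score is not named either. It ran from 1.34 to 233.1 in the series-wide list, from 50.0 to 3233.1 in replicate 1 and from 50.1 to 3100 in replicate 2, so its levels were not set against each other across lists. It served to rank, filter and compare peaks within a list, and for a correlation between the replicate lists over shared peaks. In the replicate lists many peaks share the score of 3100 (108 in replicate 1 and 64 in replicate 2), which leaves the tied peaks without a ranking among themselves. When the highest peaks of a list were taken, every peak tied with the last one was included, a rule set after the ties were seen.

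The peaks were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, and plotted with matplotlib 3.10.9. The length of each chromosome was taken as the largest peak end in the 3 lists. The 13 mitochondrial peaks of the series-wide list were left out of all comparisons. Overlap between lists meant at least 1 shared bp, and its chance level came from 1000 random rotations of the other list within each chromosome. The share of peaks on I and IV was tested by 100000 random rotations of the peak set along the 6 nuclear chromosomes joined end to end, and shares in chromosome ends (outer 10% on each side) and arms (outer 30%) by 100000 rotations within chromosomes. Peaks were placed by their midpoints. Densest windows of 100 kb were compared with 1000 uniform placements. Scores were compared by 100000 permutations over peaks, and top peaks by Fisher's exact test. All p-values came from tests with peaks as units, and no test across the 2 libraries was run. Benjamini-Hochberg adjustment was made over 6 chromosomes or 12 ends, with a threshold of 0.05.

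The rotation tests were tested on simulated sets of 6646 peaks, placed in clusters of 1 to 10 peaks within 10 kb. Apart from the raised densities named below, the clusters were spread uniformly. They lacked the excess in the arms and the dense windows of the real lists. The runs therefore do not show how often the tests pass by chance in lists with such structure. With no effect, 3 of 50 simulated sets passed for the share on I and IV and 1 of 50 for the share in the ends. With a density raised 1.4 times on I and IV, 50 of 50 passed, and with a density raised 1.4 times in the ends, 49 of 50 passed.

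Comparisons, settings and the rule for naming sites were fixed before the data were examined. The named sites were the 10 highest series-wide peaks, the 3 highest of each chromosome, the densest window of each chromosome and the strongest peak of each replicate, with ties broken by chromosome and start. The comparison of X in the 100 highest peaks was added, and stretches with several of the 100 highest peaks were named, after their values were seen. The alternatives were stricter score thresholds, merging of peaks within 10 kb, other overlap rules, other window and end sizes, covered bases in place of peaks, and each replicate's own list. A planned search for sequence motifs and a planned comparison with gene classes and fixed gene lists were not run: no genome was used here, and the gene table at hand is on the assembly WBcel235, another build than that of the peaks.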

Results

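ZIM-3 is a zinc finger protein of the nematode Caenorhabditis elegans that is needed in meiosis for the pairing of chromosomes I and IV. It acts at pairing centers, regions towards 1 end of each chromosome through which homologous chromosomes find each other. The series mapped its binding by chromatin immunoprecipitation with an affinity-purified rabbit antibody, followed by sequencing (ChIP-seq). The animals were hermaphrodites of the strain fem-2(b245), which carries a mutation in a gene of the sex determination pathway, kept at 20 °C. Their stage is labelled as young adult with a germline, while the growth protocol speaks of gravid adults. The group held 2 ChIP samples, numbered as replicates 1 and 2, and 2 samples of input DNA, which have no peak list here. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. No other strain, antibody or stage was compared, so the comparisons were those between the replicates and between chromosomes or parts of chromosomes.

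The authors' peak lists held 6079 peaks for replicate 1, 1211 for replicate 2 and 6659 in the list of the whole series (the series-wide list). The median peak width was 293 bp in replicate 1, 439 bp in replicate 2 and 279 bp in the series-wide list. Peaks covered 2.86% of the nuclear genome in replicate 1, 0.948% in replicate 2 and 3.18% in the series-wide list. The files give neither read counts nor depth per library, so the depth behind each peak is unknown. Peak scores are the authors' own; their levels are read within each list, and between the replicate lists they enter only a correlation over shared peaks. In replicate 1, 127 peaks scored 3100 or more, and in replicate 2 the highest score of 3100 was shared by 64 peaks. Positions are on the WormBase build WS220; gene annotation was not used with them, so sites are described by chromosome and position.

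The highest-scoring sites lay close together near the left tip of chromosome IV. The 3 highest series-wide peaks were at IV 195277 to 197054 (score 233.1), IV 215444 to 216492 (score 150) and IV 124502 to 125497 (score 146). The peak at IV 229730 to 231197 ranked seventh with a score of 125. These 4 peaks fell within 107 kb and lay in the first 1.32% of the chromosome. Each overlapped a peak in both replicates. At the strongest site both replicate lists gave 3100, a score that 108 peaks share in replicate 1 and 64 in replicate 2. At the third site they gave 2223 in replicate 1 and 2362 in replicate 2.

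On chromosome I the strongest sites lay towards the right end. The leading peaks were at I 14413560 to 14415487 (score 138), I 13589328 to 13591725 (score 123) and I 10968479 to 10970369 (score 113). At the third of these, replicate 1 gave a score of 160 and replicate 2 a score of 3100. Whether the 2 lists score on the same scale is not given. Of the 100 highest series-wide peaks, 9 lay between I 13276816 and I 14117035, and all 9 overlapped peaks of both replicates. The remaining 4 of the 10 highest peaks were on chromosome X, at X 6296259 to 6296716 (score 136), X 11093887 to 11094295 (score 125), X 4208971 to 4209377 (score 116) and X 806496 to 806846 (score 115). These X peaks were between 351 and 458 bp wide, whereas the 4 leading peaks of chromosome IV were between 996 and 1778 bp wide.

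**Figure D1:**
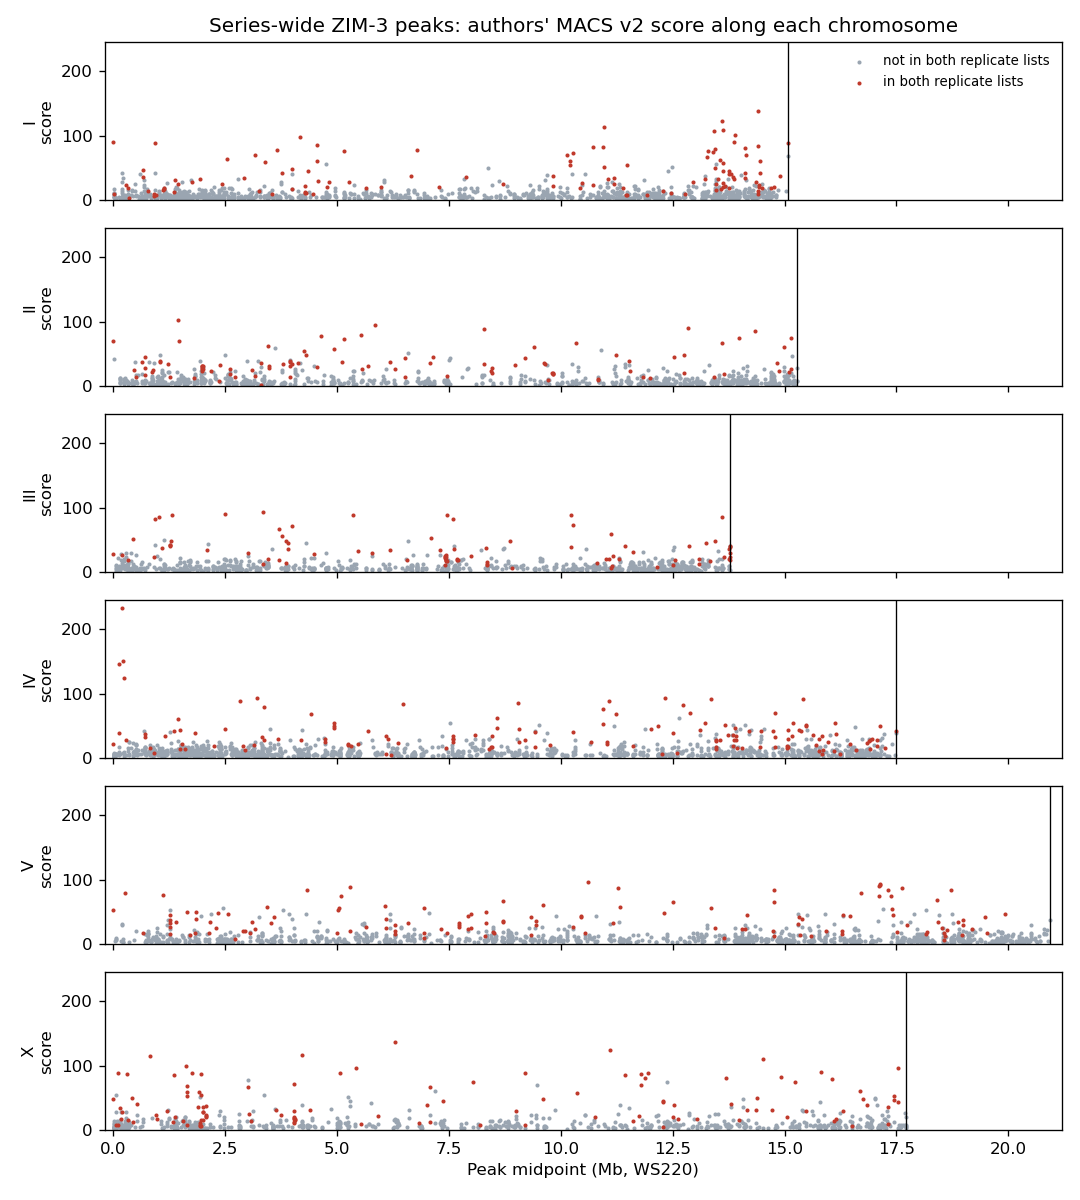
Each point is 1 series-wide peak, placed by its midpoint in Mb on WS220 (x axis) and the authors' score (y axis), with 1 panel per chromosome; red points overlap peaks of both replicates, grey points do not, and the vertical line marks the chromosome's end. The 4 peaks near the left tip of IV reach scores from 125 to 233.1, and 9 of the 100 highest peaks stand between 13.28 and 14.12 Mb on I.

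**Figure D2:**
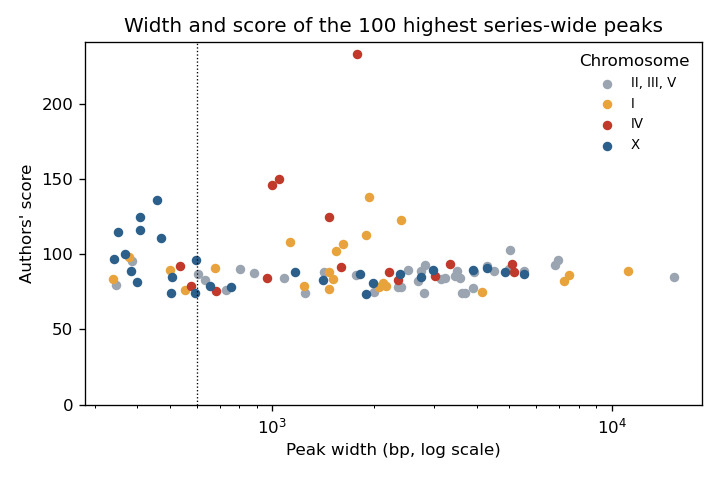
Each point is 1 of the 100 highest series-wide peaks, with its width in bp (x axis, log scale) and the authors' score (y axis), coloured by chromosome; the dotted line marks 600 bp. The 4 leading peaks of IV are 996 to 1778 bp wide, and the 4 leading peaks of X are 351 to 458 bp wide.

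The leading sites of the other autosomes scored below the 10 highest peaks. On chromosome II they were at II 1450353 to 1455385 (score 103), II 5844590 to 5844976 (score 95.5) and II 12843636 to 12846153 (score 89.7). On chromosome III they were at III 3334221 to 3337034 (score 93.0), III 2496889 to 2501878 (score 90.4) and III 1299630 to 1303132 (score 89.1). On chromosome V they were at V 10605573 to 10612525 (score 96.3), V 17119866 to 17126685 (score 93.0) and V 17127933 to 17132218 (score 92.3). The pair on the right arm of V belonged to a stretch from V 16707074 to V 17629735 that held 8 of the 100 highest peaks. The strongest peak of replicate 1 was at I 10239531 to 10241495 (score 3233.1) and had no counterpart in replicate 2. The first of the tied peaks of replicate 2 was at I 933389 to 934875.

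Chromosomes I and IV carried more peaks than their length would give. Of 6646 series-wide nuclear peaks, 2650 (39.9%) lay on I and IV, which make up 32.5% of the nuclear genome. Random rotation of the whole peak set along the joined chromosomes gave shares from 27.4% to 38.3% in its central 95% (one-sided permutation p = 0.00627). The rotations keep the local clustering of peaks but run across chromosome boundaries. The p-value therefore does not take chromosomes as units. The share was 40.3% in replicate 1 (permutation p = 0.00662) and 36.5% in replicate 2, where it did not exceed the rotations (permutation p = 0.167); a difference between the replicates was not tested. The share also missed the threshold among the 703 series-wide peaks found in both replicates, at 38% (permutation p = 0.162), and among the 664 highest-scoring peaks, at 37.7% (permutation p = 0.202).

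By single chromosome, IV had the highest density with 84.9 series-wide peaks per Mb, followed by I with 77.2, V with 67.7, III with 62.0 and II with 60.1. Chromosome X had the lowest, with 45.5 peaks per Mb. IV held 1.28 times, I 1.17 times and X 0.686 times the peaks expected from length. For I alone the two-sided permutation p was 0.289 before adjustment. None of the 6 chromosomes passed after Benjamini-Hochberg adjustment: the 2 with an unadjusted two-sided permutation p under 0.05 were IV (p = 0.0124, adjusted p = 0.0744) and X (p = 0.0424, adjusted p = 0.127). In replicate 2 the densities were nearer to each other, from 10.5 peaks per Mb on V to 14.2 on IV, with 11.1 on X. Of the 248 replicate 2 peaks on IV, 39 lay in IV 6600001 to 6800000, its 2 densest windows of 100 kb. Without the 2 densest windows of each chromosome, a setting chosen after seeing the data, IV had 12.1 peaks per Mb in replicate 2, I had 11.6 and the others had 8.88 to 9.75.

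**Figure D3:**
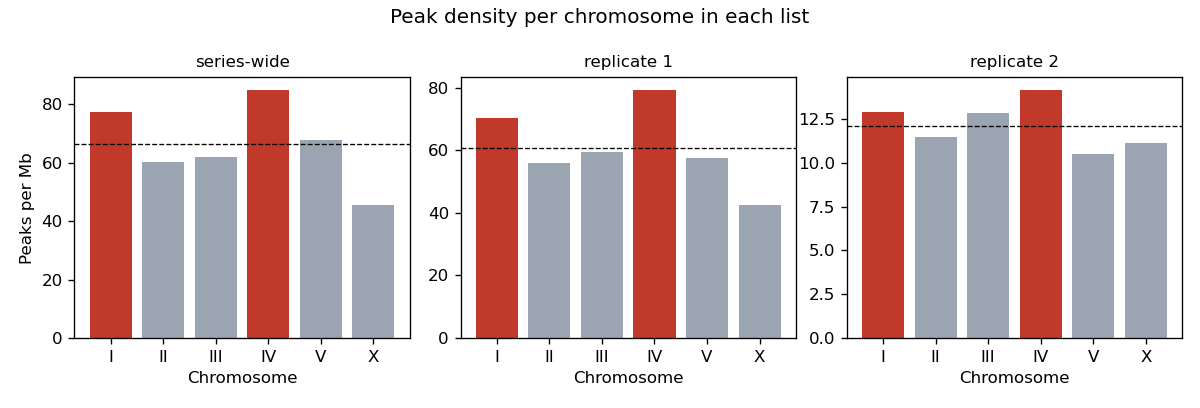
Bars give the number of peaks per Mb on each nuclear chromosome in the series-wide list, replicate 1 and replicate 2 (panels with separate y axes from 0), with I and IV in red; the dashed line is the mean density of the list. IV stands highest in all 3 lists, and X lowest in the series-wide list (45.5 peaks per Mb) and in replicate 1 (42.6).

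Peak scores did not separate I and IV from the other chromosomes. The median series-wide score was 7.62 for 2650 peaks on I and IV and 7.46 for 3996 peaks elsewhere, a difference of 0.16 (two-sided permutation p = 0.151). The 2 replicate lists gave differences of 0.94 (p = 0.828) and -7.45 (p = 0.605) by the same permutation test, each within its own list. Of the 100 highest series-wide peaks, 37 lay on I and IV (exact 95% interval 27.6% to 47.2%), against 39.9% of the other peaks (two-sided Fisher's exact p = 0.607). For the 50 highest the share was 42% and in replicate 2 it was 45%, both above that of the remaining peaks and short of the threshold. Chromosome X held 27 of the 100 highest peaks against 11.9% of the rest, a contrast chosen after its values were seen (two-sided Fisher's exact p = 3.9e-05). Among the top peaks of the replicates' own lists X held 19 of 127 in replicate 1, ties included, and 14 of 100 in replicate 2. Of all peaks in these lists X held 12.4% in replicate 1 and 16.3% in replicate 2. The top peaks of replicate 2 thus held a lower share on X than its whole list, and those of replicate 1 a higher one. Neither contrast was tested. Peaks are not independent replicates, so these p-values describe the lists and not a spread between animals.

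Called peaks were more frequent towards the chromosome ends, with no input list to set them against. The outer 10% at both ends of the 6 chromosomes held 28.8% of the series-wide peaks, where 20.0% were expected (two-sided permutation p = 0.00178, rotation within chromosomes). The share was 29.5% in replicate 1 (p = 0.00054) and 29.5% in replicate 2 (p = 0.0174) by the same permutation test. In the outer 5% the excess missed the threshold (13.4% against 10.0%, permutation p = 0.0521). The arms, taken as the outer 30% on either side, held 73.3% of the peaks against 60.0% expected (permutation p = 2e-05). They held 73.0% in replicate 1 and 70.4% in replicate 2.

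Of the 12 single ends, the left end of X had the highest share of its chromosome's peaks. It held 189 peaks, or 23.4% of those on X, against 10.0% expected (permutation p = 0.00352, adjusted p = 0.0422 over 12 ends). That call was lost in all 6 alternatives run, with an adjusted permutation p from 0.341 to 0.802. The ratio to the expected share, 2.34, was 2.80 in the outer 5% and 1.15 after merging of peaks within 10 kb. The alternatives included the replicates' own lists, with 20.3% in replicate 1 (adjusted permutation p = 0.417) and 14.7% in replicate 2 (adjusted permutation p = 0.802). The left end of IV held 17% of the peaks of IV (adjusted permutation p = 0.41), and the right end of I held 15.7% of the peaks of I (adjusted permutation p = 0.52). In replicate 2, 28.9% of the peaks of chromosome I were in its right end (adjusted permutation p = 0.762).

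Peaks were clustered on every chromosome. The densest window of 100 kb on chromosome V, V 8800001 to 8900000, held 60 series-wide peaks, against a chromosome mean of 6.77 and a highest value of 21 when the peaks were spread uniformly. The windows on the other chromosomes were X 1 to 100000 with 36 peaks, I 13400001 to 13500000 with 34, II 1000001 to 1100000 with 31, IV 3300001 to 3400000 with 30 and III 7400001 to 7500000 with 21. All 6 lay above the 95th percentile of the uniform placements, and the same held for the densest windows of each replicate. The series-wide window on III only equalled the highest uniform value of 21, while the other series-wide windows exceeded theirs. The 60-peak window on V had 40 peaks in replicate 1 and 0 in replicate 2, and its peaks had a median score of 5.63. The window on III had 31 peaks in replicate 1 and 35 in replicate 2, and peaks covered 45.8% of it in the series-wide list. The window on I, which lies inside the group of strong peaks, had 22 peaks in replicate 1 and 10 in replicate 2. From replicate 1 the windows on X, IV and II held 20, 24 and 24 peaks, against 2, 3 and 5 from replicate 2, the shorter list. In replicate 2's own list the densest window lay elsewhere on 5 of 6 chromosomes.

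The 2 replicates shared most of the shorter list. Of the 1211 peaks of replicate 2, 930 (76.8%, Wilson 95% interval 74.3% to 79.1%) overlapped a peak of replicate 1 by at least 1 bp, against a mean of 6.4% for rotated peaks. Of the 6079 peaks of replicate 1, 839 (13.8%, interval 13% to 14.7%) overlapped a peak of replicate 2, against 1.38% for rotated peaks. These intervals cover counting error only. With reciprocal overlap of 50% the shares were 45% of replicate 2 and 8.97% of replicate 1. Overlap rose with score, and so did peak width, from a median of 181 bp in the lowest-scoring 10% to 1290 bp in the highest in replicate 1 and from 228 to 1953 bp in replicate 2; wider peaks meet the overlap rule more easily. In the highest-scoring 10% of replicate 1, 54.6% of the peaks were found in replicate 2, and in the lowest 10% 2.8%. In replicate 2 the share went from 97.5% in the highest 10% to 69.4% in the lowest. Over 585 peaks that overlapped 1 to 1, the scores had a Spearman's rho of 0.35 and a Pearson's r of 0.40 on the log10 scale, across peaks, which are not independent replicates. Over the 505 pairs with both scores below 3100, rho was 0.17. With reciprocal overlap of 50%, rho was 0.61 over 545 pairs and 0.44 over the 462 pairs below 3100.

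**Figure D4:**
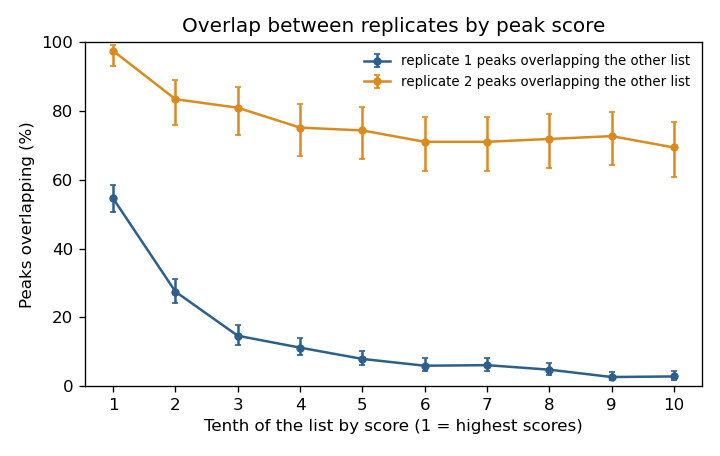
The y axis gives the percentage of peaks that overlap a peak of the other replicate, for successive parts of a list, each with 10% of its peaks, ordered by score (x axis, 1 = highest), with Wilson 95% intervals as error bars. The share falls from 54.6% to 2.8% for replicate 1 and from 97.5% to 69.4% for replicate 2.

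Most series-wide peaks overlapped a peak of replicate 1, the longer of the replicate lists. Of its nuclear peaks, 4118 (62.0%) overlapped a peak of replicate 1 alone, 703 (10.6%) of both replicates and 226 (3.4%) of replicate 2 alone. Another 1599 (24.1%) overlapped a peak of neither list. With reciprocal overlap of 50%, 425 peaks were in both replicates. The median score was 31.7 for peaks found in both replicates, 8.47 for replicate 1 alone, 6.9 for replicate 2 alone and 4.38 for neither. In the other direction, 86.5% of the replicate 1 peaks and 97.2% of the replicate 2 peaks overlapped a series-wide peak.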

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

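The series-wide list holds 13 peaks on the mitochondrial genome, while both replicate lists hold 0. They are listed as peaks outside the nuclear comparisons. The replicate lists hold only peaks above a score minimum, on another scale, so their count of 0 sets no limit on mitochondrial signal. The peaks run from position 118 to position 13806, cover 76.0% of the sequence up to there, and score from 2.83 to 21.9 with a median of 6.48. No control list was at hand to set beside them.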

How the results depend on the processing

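The autosomes-only share, the share without the densest windows, the shares of the 10 and 20 highest peaks and the densities in replicate 2 without dense windows were chosen after seeing the data. The share of peaks on chromosomes I and IV stayed above the length share in each setting run. It missed the threshold in the 664 highest-scoring peaks (37.7%, permutation p = 0.202), in the 703 peaks found in both replicates (38%) and in replicate 2's own list; the replicates' own lists gave 36.5% to 40.3%. On autosomes it was 45.4% against 39.4% by length (permutation p = 0.019). The excess in the chromosome ends missed the threshold in the outer 5% (13.4% against 10.0%, permutation p = 0.0521), and that in the arms passed in all settings run. The call for the left end of X was lost in all 6 alternatives (adjusted permutation p from 0.341 to 0.802; ratio to the expected share from 1.15 to 2.80, and 2.34 as reported). In replicate 2 the density of IV fell from 14.2 to 13.1 peaks per Mb without the densest window of each chromosome and to 12.1 without the 2 densest, and stayed the highest of the 6 in both. None of the 6 chromosomes passed singly in any setting run. Overlap between replicates depended on its definition. With reciprocal overlap of 50% it fell to 8.97% of replicate 1 and 45% of replicate 2, with centers within 200 bp to 9.97% and 50.1%, and with equal numbers of top peaks it was 41% and 53.3%. The count of series-wide peaks in both replicates fell from 703 to 425 under the reciprocal rule, and the rho of scores was 0.61 against 0.35. The rho over pairs below 3100 was 0.17. The densest windows moved with the setting: they began elsewhere on 4 of 6 chromosomes with windows of 50 kb, 3 with 200 kb, 5 in replicate 2's list and 1 in replicate 1's. On V the window began at 2350001 with 50 kb and at 2400001 with 200 kb, and in replicate 2's list, which is shorter, the count on I was 11 against 34 and that on III 35 against 21. The difference in median score between I and IV and the other chromosomes ran from -7.45 in replicate 2's list to 0.94 in replicate 1's. The share of top peaks on I and IV, 37% for the 100 highest, was above that of the other peaks for the 50 highest (42%), the 10 highest (60%), the 20 highest (55%) and in replicate 2; the replicates' own lists gave 37% to 45% for the 100 highest with ties. For other numbers of top peaks they gave 35.9% (replicate 2, 64 tied peaks) to 70% (replicate 1, 7 of the 10 highest, two-sided Fisher's exact p = 0.101), and none of these passed the test. The cause of these changes was not tested. The alternatives planned for gene classes and sequence motifs were not run. Depth is unknown, so a peak missing from replicate 2 is no evidence of absent binding. No paired analysis was possible because the input samples have no peak list here and the ChIP samples form a single group.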

Other observations

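All tests in this part, and the sites named here, were chosen after the values were seen. The left chromosome tips carried peaks in all 3 lists. A peak started within the first 100 bp of each of the 6 chromosomes in the series-wide list, in replicate 1 and in replicate 2. The mean density of peaks gives 0.0398, 0.0365 and 0.0073 such starts. Called peaks were more frequent towards the ends, so these values are a low yardstick. No input list was at hand for the tips, and binding there was not tested. At the left tip of I the peak reached position 500 with a score of 89.8. At the right tips, whose position was itself taken from the last peak of any list, a peak ended within the last 2000 bp of 6 chromosomes in the series-wide list, 4 in replicate 1 and 3 in replicate 2. The sequence under these peaks was not examined.

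Strong peaks stood in groups on the right arm of I (9 of the 100 highest within 1 Mb) and near the left tip of IV (4 of the 100 highest), and all 13 overlapped peaks of both replicates. Neither trait was particular to I and IV. The fullest windows of 1 Mb held 8 of the 100 highest on V, 5 on X, 3 on III and 2 on II. All of these overlapped peaks of both replicates too. For I, the scores were shuffled over the fixed peak positions. A window of 1 Mb as full on any chromosome came up in a share of 0.0148 of 10000 shuffles. Shuffling among peaks of like width gave 0.008, and windows of 500 and 2000 kb gave shares from 0.0046 to 0.0273. That argues only against peak density or width acting alone, with scores independent between neighbouring peaks. This independence was not tested, and neighbours that score alike would make full windows more frequent than in the shuffles. For IV the same shuffles gave a window on IV with 4 or more of these peaks in shares of 0.897 and 0.762, so the count alone does not set this group apart, and its high ranks and short span were not tested. Binding at the pairing centers of I and IV is a candidate explanation. It stays open, since the positions of the pairing centers were not used here and no input list was at hand. The window on I held 1.125 times the 8 top peaks of the fullest window elsewhere, on V, while X held 5. Such a ratio of counts cannot decide, since it does not place the peaks at or away from a pairing center. Its limit was also set after the values were seen. Such a count also does not bear on the group of IV, with its 4 top peaks.

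Of the 27 X peaks among the 100 highest, 13 were under 600 bp wide, against 8 of the 73 on other chromosomes, with medians of 658 and 2122 bp. Compared with the largest width difference of any of the 6 chromosomes under permutation, X peaks were narrower (permutation p = 0.0124), which argues against a score that favours narrow peaks on every chromosome alike. Outside the top 100 the ratio of median widths, X to the others, was 0.982 (95% bootstrap interval 0.92 to 1.02), which argues against narrower X peaks at every score. Of the 13, 12 overlapped peaks of both replicates. The pattern was not seen among the top peaks of the replicates' own lists. There 0 X peaks were under 600 bp, and on the other chromosomes 0 of 108 in replicate 1 and 1 of 86 in replicate 2. Median widths on X were 3318 against 2509 bp in replicate 1 and 3132 against 2014 bp in replicate 2. Scores rose with width in these lists, so narrow peaks were nearly absent from their top on every chromosome. They therefore cannot decide on the pattern. Recruitment sites of the dosage compensation complex, which binds X in hermaphrodites, are a candidate explanation that stays open, since 0 of the 13 could be set against such sites, whose coordinates were not used here.

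Some of the strongest peaks of replicate 1 shared a width and were missing from replicate 2. Of the 127 replicate 1 peaks scoring 3100 or more, 32 had no overlapping replicate 2 peak, and 11 of these 32 were between 1232 and 1285 bp wide, on 5 chromosomes (for example IV 7524347 to 7525584, V 18151050 to 18152281 and X 53212 to 54462). Random draws of 32 of the 127 peaks gave at most 10 peaks within any 100 bp of width. The one-sided permutation p was 1e-05, the smallest that 100000 draws can give. That argues only against a loss of peaks in a shorter list without regard to width. Wider peaks meet the overlap rule more easily, and a loss that depends on width was not tested. The range of 100 bp that starts at 1232 bp also held 3 of the 95 peaks scoring 3100 or more that had a replicate 2 peak. In all, 101 replicate 1 peaks of any score lay in it. The series-wide list calls all 11 sites, with widths of 1092 to 1143 bp and scores of 42.9 to 56.5. Copies of a repeated element are a candidate explanation that stays open, since the sequence of 0 of the sites was examined.

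Replicate 2 had dense stretches that replicate 1 lacked. In IV 6600001 to 6700000 replicate 2 had 19 peaks and replicate 1 had 0, and in IV 6700001 to 6800000 they had 20 and 1. The series-wide list had 25 and 24 peaks there, with median scores of 4.14 and 5.12. In V 6000001 to 6100000 replicate 2 had 24 peaks and replicate 1 had 6. The reverse held in V 8800001 to 8900000, with 40 peaks in replicate 1 and 0 in replicate 2.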
